A study of Mus musculus with 2254 samples.

How the data were processed

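Single cells were sorted by fluorescence from the brains of adult SM22-Cre;Rosa26-stop-tdTomato mice, in which a smooth muscle promoter drives a red reporter, into 384-well plates. They were sequenced by Smart-seq2, which makes full-length cDNA from polyadenylated RNA. Each GEO sample was 1 cell, and the labels gave 1127 cells as Notch3 KO and 1127 as Notch3 WT. The cell names placed them on 6 plates, with KO cells on plates 043, 467 and 471 and WT cells on plates 044, 468 and 469. Plates 043 and 044 were taken as the earlier batch and the other 4 plates as the later batch, from their numbers alone. Sort gates were not described.

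The authors deposited raw read counts per gene symbol and cell, and the values were whole numbers that summed to a different total in each cell. Per the submitters' processing notes, reads were aligned with TopHat2 2.1.1, handled with SAMtools 0.1.18 and counted with featureCounts from Subread 1.4.6-p5 on genome build GRCm38 (mm10). The version of the authors' gene annotation, the strand setting and any cell filter were not given in the sources used here. The lowest total of any deposited cell was 49473 counts and the lowest number of detected genes was 1448. Of the 30950 table entries, 27956 (90.3%) matched a symbol of GENCODE release M21 for GRCm38, which gave coordinates, transcript length and GC content. Every column of cells was used, with 0 columns left out.

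The labels named no animal, donor or culture, so each genotype counted as 1 sample and no statistical test was possible between genotypes. No p-value or standard error was computed for a difference between genotypes. Standard errors by resampling cells or genes served only to weigh explanations of the Notch3 level on plate 044. Values are given per plate, with the SD over plates as a description, and a difference was described by its size and by whether the plates of the genotypes overlapped. Exact binomial (Clopper-Pearson) and exact Poisson intervals at 95% covered counting error only, since reads amplified by PCR without molecular identifiers are not independent molecules. The limit that a count of 0 allows was taken as 3 counts or 3 cells over the group. Folds against 3 counts used counts pooled over plates. They are not lower bounds, since reads of the same cell are not independent.

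The following choices were made before the data were examined: the cell filter, clustering settings, marker lists, gene lists, size rule, rule for named genes and the alternatives not named below as later choices. Cells needed at least 50000 counts and 1000 detected genes, which kept 2252 cells and left out 2. The table held no UMIs. Cells were clustered on 2000 variable genes without Notch3, 30 principal components, 20 exact nearest neighbours and the Leiden method at resolution 1 (leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0), which gave 19 clusters. No doublet caller was run, because each well was meant to hold 1 sorted cell. Leaving out the 121 cells with markers of a second class above the 99th percentile was an alternative.

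A cluster was named after the best of 14 marker lists if the list's mean level, scaled to the highest cluster, was at least 0.8. At least 3 markers had to be detected in 25% of the cluster's cells, and no other list could have more genes among its top 10 by fold. These naming thresholds were set after the cluster tables were seen. They left clusters 2, 15, 18 and 19 unnamed, which held 18.4% of KO and 9.87% of WT cells as means over plates. The marker lists were smooth muscle cell, pericyte, endothelial, fibroblast, microglia or macrophage, astrocyte, oligodendrocyte, oligodendrocyte precursor, neuron, ependymal, choroid plexus epithelium, lymphocyte, neutrophil or monocyte, and erythrocyte.

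Counts were summed per plate and class where a plate had at least 10 cells of the class, and scaled to CPM, the usual unit of counts relative to the library total, with TMM factors from edgeR 4.0.16 in R 4.3.3. Differences are KO minus WT in the mean log2(CPM + 1) over plates, so the pseudocount of 1 CPM shrinks the values of weakly expressed genes. The size rule required a mean of at least 10 CPM, at least 1 read in 10% of the cells of the class in 1 genotype or the other, at least a 2-fold difference, and no overlap between KO and WT plates. Chance alone keeps plates apart for 10% of genes with 3 plates against 3, and for 20% with 2 against 3. The classes with enough cells were these 4: smooth muscle-like, fibroblast-like, ependymal-like and endothelial-like. The planned comparison of pericyte-like cells, and of the KO difference between them and smooth muscle-like cells, was not made, since clustering and naming gave 6 pericyte-like KO cells. That number depended on how cells fell into clusters, and 68 KO cells were pericyte-like when all 2254 cells were clustered.

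Named genes were Notch3, the 10 largest and 10 smallest log2 differences among genes that met the size rule in each class, and up to 4 members of each gene list with the largest absolute difference. A few genes that this rule named are not reported here. Spike-in and transgene entries, sex-linked genes and gene models named only by Gm plus a number or ending in Rik were left out. For each of 22 gene lists, the median log2 difference of the members that passed the expression filter was placed among 10000 random lists of the same size matched on mean expression. The range of the random lists covers neither the spread between plates nor genes of a list that vary together. A list with fewer than 3 measured members got no percentile. The lists were Notch pathway, Notch3-linked arterial genes, contractile apparatus, ion channels and calcium handling, vasoactive receptors and signalling, basement membrane, interstitial matrix and elastic fibre, PDGF and TGF-beta signalling, blood-brain barrier and transport, arterial endothelial, venous endothelial, immediate early, heat shock, endoplasmic reticulum stress, interferon response, inflammation and adhesion, mitochondrially encoded, oxidative phosphorylation, glycolysis, cholesterol synthesis, cytosolic ribosome and cell cycle. They came from general knowledge and not from these cells, and some genes stood on more than 1 list.

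The size rule was tested on simulated data with known 3-fold and 6-fold changes in 100 genes each, drawn from the means and depths of the real plates. In the smooth muscle-like simulation of 9337 genes it recovered 91% of the 3-fold and 100% of the 6-fold changes, and 106 unchanged genes also met it. In the fibroblast-like simulation of 10528 genes these values were 67%, 85% and 475 genes. In the ependymal-like simulation of 10700 genes they were 72%, 91% and 379 genes. In the endothelial-like simulation of 9979 genes they were 72%, 95% and 718 genes.

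Alternatives were DESeq2 1.42.0 size factors, total counts without composition factors, equal weight for each cell, thinning to 50000 counts, a pseudocount of 5 CPM, expression filters of 1 and 50 CPM, a fold of 1.5, the fold rule alone, stricter and looser cell filters, resolution 2, classes from marker levels without clusters, each plate left out in turn, and each batch alone. Alternatives that reweighted or moved smooth muscle-like clusters, gaps of at least 2-fold, 3-fold or 4-fold between the nearest plates, and the windows around Notch3 were chosen after seeing the data. Other computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9.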

Results

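The data were read counts for 2254 single brain cells, 1127 from mice labelled Notch3 KO and 1127 from mice labelled Notch3 WT, on 3 plates per genotype. Notch3 is a receptor of vascular mural cells, the smooth muscle cells and pericytes that wrap blood vessels. After filtering, 378, 370 and 378 cells remained on KO plates 043, 467 and 471, and 379, 374 and 373 on WT plates 044, 468 and 469. The median total per deposited cell was 291872 counts, with a range from 49473 to 763059. Plate medians ran from 250864 counts on KO plate 467 to 358168 on WT plate 469, and each later KO plate had a WT plate of similar depth. Reads from Y-linked genes were found in 82.1% to 93.0% of the cells of each plate. No animals were named, so there were no replicates to test, and all differences below describe these 6 plates.

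Notch3 itself was lower in KO than in WT smooth muscle-like cells in every plate comparison. Its arithmetic mean over plates was 90.3 CPM in KO and 650 CPM in WT cells. The difference of the mean log2(CPM + 1) was -2.57, or 5.92-fold (SD of log2 CPM 0.52 over 3 KO plates and 1.32 over 3 WT plates). The KO plates stood at 56.8, 103 and 112 CPM. The WT plates stood at 183, 731 and 1035 CPM, the lowest being plate 044 of the earlier batch. Log2 differences and folds from means of log2 values need not match the ratio of the mean CPM, here and below. The fold was 3.19 between the plates of the earlier batch and 8.07 between those of the later batch. Notch3 (ENSMUSG00000038146.8) lies on chromosome 17 from 32120820 to 32166852 on the minus strand of GRCm38, and its exons overlap an antisense gene model, Gm17276. The counts do not show which exons the reads came from, so reads left in KO cells cannot be assigned to a part of the gene.

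KO cells still held Notch3 reads. At least 1 read was found in 72.8% of KO and 87.7% of WT smooth muscle-like cells. After thinning each cell to 50000 counts, the share was 56.2% to 68.0% on the KO plates, 79.0% on WT plate 044 and 100% on WT plates 468 and 469. Fibroblast-like cells, which served as the background class, had 0.178 to 12.8 CPM on KO plates and 2.28 to 20.8 CPM on WT plates. In the unnamed cluster 2, whose cells expressed Acta2 and Rgs5, Notch3 was 101, 121 and 131 CPM on the KO plates and 478 CPM on WT plate 044. Pericyte-like cells of WT plates 468 and 469 had 1025 and 939 CPM. The Notch3 differences in fibroblast-like (-0.24), ependymal-like (0.74) and endothelial-like cells (-0.61) did not meet the size rule.

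**Figure D1:**
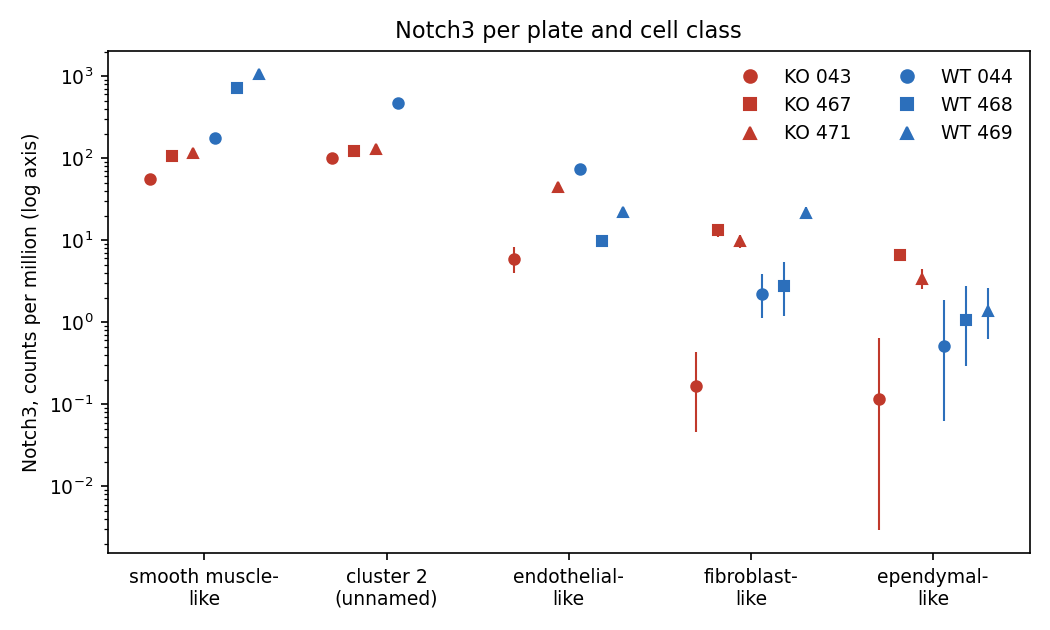
Notch3 in CPM without TMM factors on a log axis, for the plates with at least 10 cells of each class shown and of cluster 2; bars are exact 95% Poisson intervals for counting error. Smooth muscle-like cells of the 3 KO plates lie below those of the 3 WT plates, with WT plate 044 nearest to them.

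Smooth muscle-like cells were the largest class on every KO plate, and 2 of the WT plates held many more endothelial-like, astrocyte-like and macrophage/microglia-like cells. Smooth muscle-like cells made up 47.1%, 41.6% and 61.1% of KO plates 043, 467 and 471, and 81.8%, 7.49% and 13.9% of WT plates 044, 468 and 469 (means 49.9% ± 10.1 and 34.4% ± 41.2, SD, n = 3 plates). The exact 95% binomial intervals were 77.5% to 85.5% for plate 044 and 5.03% to 10.6% for plate 468. Fibroblast-like cells were 11.6% ± 4.26 in KO and 3.46% ± 0.45 in WT, and ependymal-like cells were 14.6% ± 11.0 and 3.65% ± 1.10. The plates of the genotypes did not overlap for either class. Endothelial-like cells were 3.54% ± 1.04 in KO and 14.3% ± 11.9 in WT. Astrocyte-like cells were 46.0% and 24.4% of WT plates 468 and 469 and at most 0.529% of every other plate. Macrophage/microglia-like cells were 0 of 378 cells on KO plates 043 and 471, which allows a share of up to 0.794%, and 0 of 370 on KO plate 467, which allows up to 0.811%. They numbered 54 in WT, all but 1 of them on plates 468 and 469. Oligodendrocyte-like cells were 1.15% in KO and 3.57% in WT, and pericyte-like cells 6 of the KO and 28 of the WT cells. The direction for pericyte-like cells depended on clustering and naming. When all 2254 cells were clustered anew, 2 more than before, 68 KO and 52 WT cells were named pericyte-like, and unnamed KO cells fell from 207 to 28. No cluster was named for the other 6 marker lists at resolution 1, but at resolution 2 a cluster of 19 cells was neuron-like and the oligodendrocyte-like cluster held 34 cells instead of 53. The sort gates were not described and can set these shares.

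The smooth muscle-like class held 6 clusters. Cluster 1 was led by Actg2 and Cnn1, cluster 4 by Kcna5, Map3k7cl and Pln, and cluster 8 by Rasd1 and Ppp1r15a, a stress gene. Cluster 6 was led by the immediate early genes Fosl2 and Fosb and held 154 KO and 14 WT cells. Cluster 11 was led by Ptgs2 and Rarres1 and held 72 KO and 9 WT cells, and cluster 12 was led by Pappa2 and Dmp1. Cluster 5 was fibroblast-like (Lum, Slc6a13, Dcn) and cluster 3 ependymal-like (Ccdc153, Tmem212). Endothelial-like cluster 9, led by Slco1a4 and Kdr, held 12 KO and 144 WT cells, while endothelial-like cluster 16, led by the arterial genes Gkn3 and Bmx, held 28 KO and 16 WT cells. Clusters 7 and 10 were astrocyte-like, cluster 13 macrophage/microglia-like, cluster 14 oligodendrocyte-like and cluster 17 pericyte-like. The unnamed cluster 2 held 181 KO and 39 WT cells, and cluster 18, with Ccl11 and Cxcl1 among its leading genes, held 26 KO cells and 1 WT cell. The unnamed clusters 15 and 19 held 52 and 19 cells, all of them WT.

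**Figure D2:**
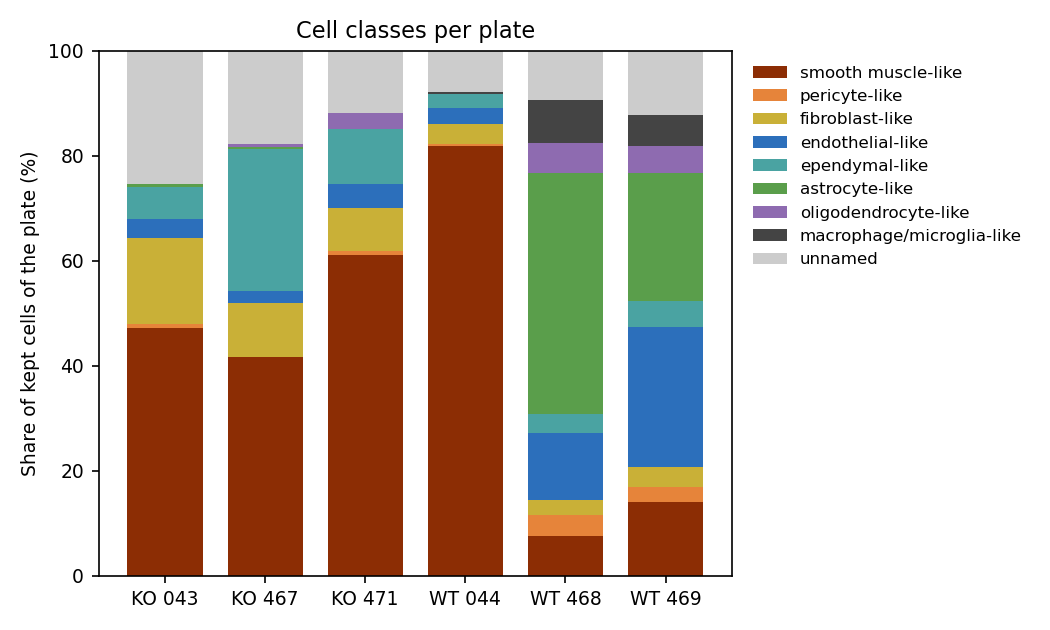
Share of kept cells, in percent, that fell in each class on each plate. WT plates 468 and 469 hold most astrocyte-like, endothelial-like and macrophage/microglia-like cells, and WT plate 044 has the highest share of smooth muscle-like cells, 81.8%.

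Among the classes of the WT plates, Notch receptors, ligands and targets differed in level, which gives the background for the loss of Notch3. Notch3 averaged 982 CPM in pericyte-like cells of plates 468 and 469, and 655 CPM in smooth muscle-like cells of all 3 WT plates, including 175 CPM on plate 044. The classes were measured on different sets of plates, so these means do not rank them. Its level was 92.9 CPM in astrocyte-like, 35.3 in endothelial-like, 16.0 in oligodendrocyte-like, 8.86 in fibroblast-like, 0.994 in ependymal-like and 0.426 in macrophage/microglia-like cells. Notch1 was 835 CPM in pericyte-like, 258 in astrocyte-like and 234 in endothelial-like cells. It was 175 CPM in smooth muscle-like cells, where the WT plates ran from 71.8 to 254 CPM. Notch2 was 242 CPM in fibroblast-like and 269 in macrophage/microglia-like cells, and Notch4 was 121 CPM in endothelial-like cells. The ligand Jag1 was 383 CPM in smooth muscle-like and 200 in endothelial-like cells, while Dll4 was 96.4 CPM in endothelial-like cells. The target gene Heyl was 716 CPM in smooth muscle-like and 627 in pericyte-like cells, and Hes5 was 172 CPM in astrocyte-like cells and at most 4.35 in the other classes.

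In smooth muscle-like cells, the question was what else differed where Notch3 is normally abundant. Collagen VI genes, Fhl2 and Nrp2 were higher in KO cells, and Casq2, Vipr2 and Stc2 were lower. Of 25 contractile apparatus genes, 18 were lower in KO, but 0 met the size rule. Of 9403 measured genes, 182 were higher and 93 lower in KO by the size rule, from 563 KO and 390 WT cells. WT plates 044, 468 and 469 held 310, 28 and 52 of these cells. Shares of WT cells with a gene therefore mostly describe plate 044, while the differences weigh the plates equally. Acta2, the smooth muscle actin, averaged 5512 CPM in KO and 5513 CPM in WT cells. Tagln stood lower, at 1441 to 1543 CPM on the KO plates and 1700 to 2315 CPM on the WT plates. Plates did not overlap for 10.3% of the measured genes, against the 10% that chance gives.

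The largest difference upward was in Fhl2, a LIM-domain protein, with 64.1 CPM in KO and 1.04 CPM in WT cells (log2 difference 5.32; SD of log2 CPM 0.10 and 1.15, n = 3 plates each). It was found in 23.8% of KO and 2.82% of WT cells. Col6a1 and Col6a2, which encode chains of collagen VI, had log2 differences of 5.28 and 3.58, and Col6a2 was found in 56.7% of KO and 24.6% of WT cells. Nrp2, a co-receptor for semaphorins and VEGF, differed by 4.90 and the chemokine Cxcl1 by 4.74. Enpp2, which encodes autotaxin and overlaps an antisense gene model, differed by 3.96, Rarres1 by 3.80, Kank4 by 3.70 and Fxyd6 by 3.66. Rarres1 was also a leading gene of cluster 11, and its difference was 1.06 when clusters 1, 4 and 8 were weighted equally, while that of Cxcl1 was 3.05. Kank4 differed by 1.98 when cluster 2 was added to the class. Within plates 043 and 044 the differences were smaller, at 3.97 for Fhl2, 3.34 for Col6a1, 1.59 for Col6a2, 4.19 for Nrp2, 1.93 for Cxcl1, 2.71 for Enpp2, 2.05 for Rarres1, 1.54 for Kank4 and 2.68 for Fxyd6. Within the later plates they were 6.02, 6.27, 4.58, 5.26, 6.18, 4.60, 4.70, 4.80 and 4.17 in the same order.

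The largest differences downward were in Atp13a5 (-4.20), a pericyte marker, and Sp6 (-3.76), whose exons overlap the antisense model Gm11532. With cluster 2 added these were -1.77 and -2.38, and with clusters 1, 4 and 8 weighted equally Sp6 differed by -1.87. Vipr2, a receptor for vasoactive intestinal peptide, had 2.18 CPM in KO and 36.0 CPM in WT cells (-3.53) and was found in 2.13% and 10.3% of them. Stc2 differed by -3.41. Casq2, which binds calcium in the sarcoplasmic reticulum, had 12.2 CPM in KO and 127 CPM in WT cells (-3.30) and was found in 4.09% and 24.1% of them. Lsamp (-2.01), the potassium channel gene Kcna2 (-1.98), Chn2 (-1.97), which overlaps antisense gene models, and Map3k7cl (-1.79) were also lower. Map3k7cl was found in most cells, 73.5% of KO and 88.7% of WT, and differed by -0.59 within the earlier batch and -2.39 within the later. Lsamp differed by -1.07 and -2.48 in the same order, Kcna2 by -2.02 and -1.96, and Chn2 by -2.39 and -1.76. Without WT plate 044, 853 genes met the rule, without WT plate 469 it was 415 and without KO plate 043 it was 431. Plates 043 and 044 alone gave 423 genes and the later plates alone 851.

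**Figure D3:**
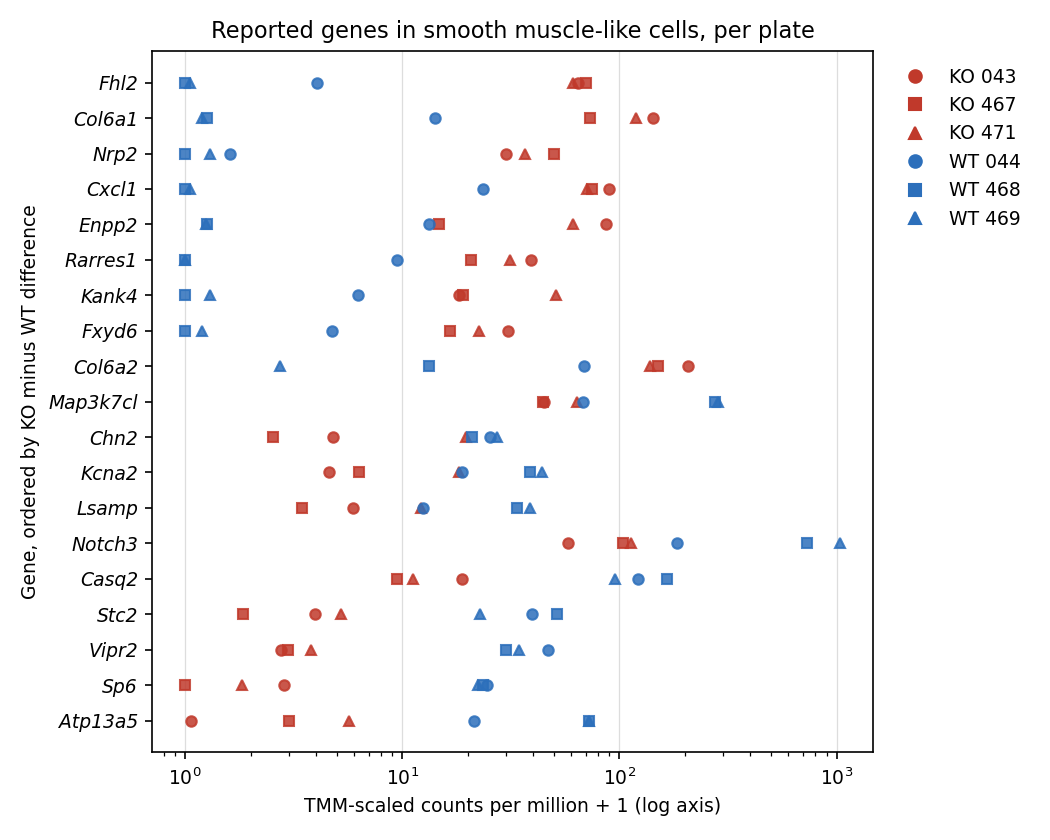
CPM plus 1 on a log axis for 19 genes named by the rule in smooth muscle-like cells, 1 point per plate, KO in red and WT in blue. For Fhl2 the KO plates lie at 60.3 to 68.9 CPM and the WT plates at 0 to 3.07 CPM.

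Of the 22 gene lists, 9 lay outside the central 95% of matched random lists in smooth muscle-like cells. The Notch3-linked arterial genes had a median of -0.54 over 10 genes, and 9 of them were lower in KO, but only Kcna5 met the size rule (-1.17). Xirp1 (-0.94) and Grip2 (-0.88) did not. Ion channels and calcium handling had a median of -0.29 over 22 genes, with Casq2 and Kcna5 lower and Kcnj8, a subunit of the vascular ATP-sensitive potassium channel, higher (2.44). Kcnj8 was also on the pericyte marker list, with 1192 CPM in pericyte-like and 25.2 CPM in smooth muscle-like cells. All 14 measured genes of cholesterol synthesis were lower, with a median of -0.32, and 0 met the rule; Lss had the largest difference (-1.31). The Notch pathway list itself had a median of -0.15 over 14 genes, inside the random range. Of its members only Nrarp, a target and feedback inhibitor of Notch, met the rule, with 59.4 CPM in KO and 132 CPM in WT cells (-1.13). The targets Hes1 (0.14), Heyl (-0.12) and Hey2 (-0.31) did not.

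Interstitial matrix and elastic fibre genes had a median of 0.53 over 20 genes, and 4 met the rule, all of them higher, among them Col6a1, Col6a2 and Col3a1 (1.58). Inflammation and adhesion genes had a median of 0.84 over 9 genes, with Cxcl1 and Tnfaip3 (1.69) meeting the rule. Ptgs2, which encodes cyclooxygenase 2 and led cluster 11, had a difference of 5.02 with overlapping plates. Venous endothelial genes had a median of 0.93 over 4 genes, with 1 of them higher by the rule. Interferon response genes had a median of 0.49 over 11 genes and 0 met the rule. PDGF and TGF-beta signalling had a median of 0.22 over 17 genes, with 2 genes higher by the rule, among them Acvrl1 (1.96), and Pdgfb lower (-1.33). Immediate early genes had a median of 0.22 over 22 genes and 0 met the rule. The medians of the last 2 lists turned to -0.04 and -0.14 when clusters 1, 4 and 8 were weighted equally.

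The other 12 lists had medians inside the random range. Contractile apparatus genes had a median of -0.11 over 25 genes, with 0 meeting the rule; Synm differed most (-0.65). Basement membrane genes had a median of 0.13 over 16 genes, with Lamb1 higher (3.16). Vasoactive receptors and signalling (-0.01), blood-brain barrier and transport (0.07), arterial endothelial (-0.06), heat shock (0.16), endoplasmic reticulum stress (0.14), mitochondrially encoded (-0.15), oxidative phosphorylation (-0.15), glycolysis (-0.12), cytosolic ribosome (-0.01) and cell cycle genes (-0.16) had 0 genes meeting the rule.

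**Figure D4:**
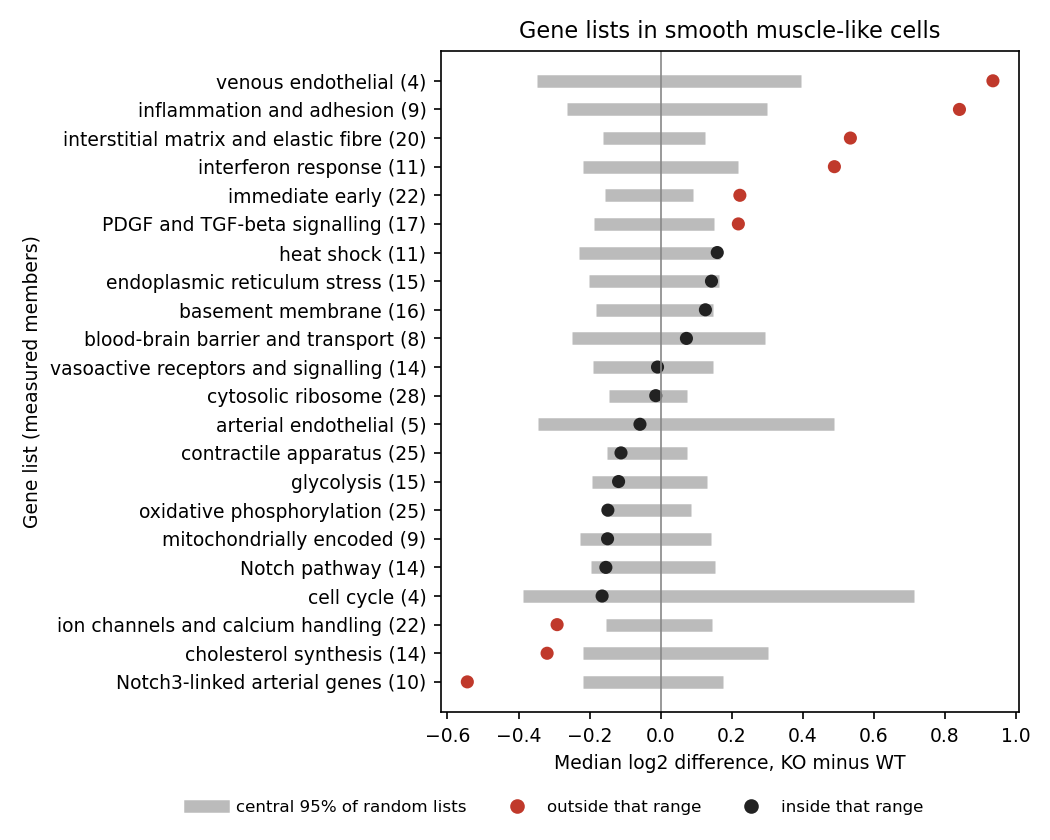
Median log2 difference, KO minus WT, of each gene list in smooth muscle-like cells, with the central 95% of random lists matched on expression as grey bars. Red points lie outside the bars, from -0.54 for Notch3-linked arterial genes to 0.93 for venous endothelial genes.

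Fibroblast-like cells had little Notch3, and a minority of their contractile and inflammatory genes was higher in KO by the rule. Of 10675 measured genes, 430 were higher and 209 lower in KO, from 131 KO and 39 WT cells, and plates did not overlap for 9.98%, against 10% by chance. WT plates 044, 468 and 469 held 14, 11 and 14 of these cells, and the median difference of all measured genes was 0.14. At resolution 2 the class split into a cluster of 93 cells led by Lum and Spp1 and 1 of 77 cells led by Slc6a13 and Slc22a6. Whether their mix differed between genotypes was not tested, so the values may also compare kinds of fibroblast-like cells. Contractile apparatus genes had a median of 0.91 over 20 genes, and 5 met the rule, among them Tagln (2.43). The chemokine Ccl7 (4.14) led the inflammation and adhesion genes, whose median was 1.15 over 14 genes with 2 meeting the rule. In plates 043 and 044 alone these medians were 0.16 and 0.010, and without cells with markers of a second class the inflammation median was 0.063. That step also left WT plate 468 out, since 9 of its cells remained, and without plate 468 alone the median was 0.37. Over 15 genes, smooth muscle transcripts in these cells stood at 1.11% to 2.25% of their smooth muscle-like level on the 3 KO plates. They stood at 1.13% on WT plate 044 and at 0.319% and 0.166% on WT plates 468 and 469.

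Pcdhb9, a protocadherin, had 43.0 CPM in KO fibroblast-like cells and 0 counts in WT. It was found in 13.0% of KO and 0% of WT cells. In counts pooled over plates it was 235-fold above a floor of 3 counts over the WT group. Folds against this floor, here and below, are not lower limits, since reads of the same cell are not independent. Plekhg4 and Gpr176 also had 0 counts in WT and were 108-fold and 143-fold above the same floor in pooled counts. They were found in 12.2% and 13.0% of KO cells. Galnt16, Hdac6, Hs1bp3, Ppp1r3b, Mtap, Traf1 and Prdm4 were the other named genes that were higher, each found in 11.5% to 29.0% of KO cells. The chemokine Ccl11 is itself a fibroblast marker and was a leading gene of the mostly KO cluster 18. It had 642 counts in WT and 0 in KO fibroblast-like cells, 677-fold lower by such a floor in pooled counts. It was found in 15.4% of WT and 0% of KO cells. Serpina1b (-4.53), a member of a family of near-identical genes whose reads are uncertain, St8sia1 (-4.26) and Hsd11b1 (-4.18), which activates glucocorticoids, were also lower. Hsd11b1 differed by only -0.35 within the earlier batch, against -6.12 within the later. Values of Galnt16, Plekhg4, Gpr176, St8sia1, Plekha6 and Zfp953 are less certain, since their exons overlap other gene models and the strand setting was not stated. Zfp775, Plekha6, Zfp953, Ptgfr and Galnt18 had differences from -3.54 to -3.25.

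PDGF and TGF-beta signalling had a median of 0.65 over 19 genes in fibroblast-like cells, with 4 meeting the rule, among them Pdgfb (2.76), Pdgfa (2.55) and Cyr61 (2.24). Cholesterol synthesis had a median of 0.75 over 16 genes and 0 met the rule. Medians of blood-brain barrier and transport (-0.61), basement membrane (-0.24), arterial endothelial (0.63) and immediate early genes (-0.33) also lay outside the random range, but each changed sign under at least 1 alternative. The other 14 lists lay inside it. Counts meeting the rule were 995 without KO plate 043, 1918 without WT plate 044, 1177 without WT plate 468 and 1257 without WT plate 469. In plates 043 and 044 alone the count was 2284 and in the later plates 2099.

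Ependymal-like cells, the ciliated lining of the ventricles, had far higher immediate early genes in KO. The list's median was 2.61 over 18 genes, and 11 were higher by the size rule while Myc was lower. Egr1 had 251 CPM in KO and 14.3 CPM in WT cells (log2 difference 4.78), Ier2 differed by 4.35, Junb by 4.22 and Btg2 by 3.79. Of 10855 measured genes, 426 were higher and 183 lower in KO, from 163 KO and 41 WT cells, and plates did not overlap for 10.9%, against 10% by chance. WT plates 044, 468 and 469 held 10, 13 and 18 of these cells, and the median difference of all measured genes was 0.12. Over 15 genes, smooth muscle transcripts stood at 0.183% to 0.299% of their smooth muscle-like level on the KO plates. They stood at 0.243%, 0.0320% and 0.291% on WT plates 044, 468 and 469. Single genes varied widely. Acta2 averaged 1042 CPM in ependymal-like and 5938 CPM in smooth muscle-like cells of all plates, and Myh11 4.54 and 4134 CPM.

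The named genes that were higher also included Col6a5, a collagen VI chain, with 365 CPM in KO and 67.1 CPM in WT ependymal-like cells (5.39). Col6a5 differed by 0.48 within the earlier batch, where WT plate 044 had 199 CPM, and by 7.87 within the later batch. It was a leading gene of the larger ependymal subcluster at resolution 2, which held 21, 75 and 32 cells of KO plates 043, 467 and 471 and 9, 0 and 1 cells of WT plates 044, 468 and 469. Ependymal-like cells of the KO and the later WT plates therefore fell mostly in different subclusters. Another higher gene was Fbxw17, with 0 counts in WT and 138-fold above the floor of 3 counts in pooled counts. It was found in 14.1% of KO cells. Fbxo7, Pdgfrl, the lipid transporter Mfsd2a (4.69), Gbp3, Id3 (4.56), Zfp446 and Raver2 completed them. Tuba1c, an alpha-tubulin, was found in 8.59% of KO and 80.5% of WT cells (-3.17), but differed by -0.17 within the earlier batch and -4.70 within the later. Nhlrc3 (-3.33), Il12rb2 (-3.17), Steap2 (-3.08), the potassium channel genes Kcnh1 (-2.95) and Kcnma1 (-2.84), and Prkg1 (-2.78) were lower, as were Mgst2, RP23-327M1.1 and Ifitm1. Fbxo7, Raver2, Nhlrc3 and Il12rb2 overlap antisense gene models.

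**Figure D5:**
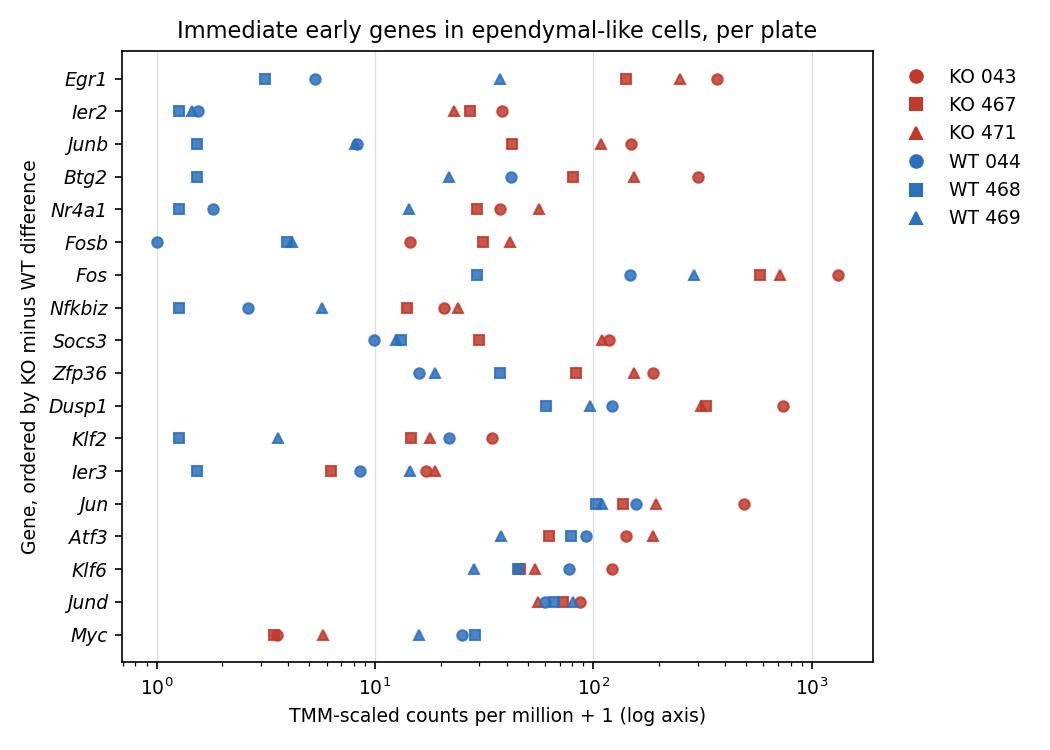
CPM plus 1 on a log axis for the 18 measured immediate early genes in ependymal-like cells, 1 point per plate, KO in red and WT in blue. KO plates lie above WT plates for 11 genes, and Myc is lower in KO.

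Of the other lists in ependymal-like cells, PDGF and TGF-beta signalling had a median of 0.93 over 12 genes with 3 meeting the rule, among them Id3 and Id1 (2.41). Interferon response genes had a median of 0.94 over 13 genes, with Gbp3 (4.57) meeting the rule, but their median was -0.02 in plates 043 and 044 alone. Contractile apparatus genes had a median of 0.42 over 16 genes and cytosolic ribosome genes 0.23 over 28 genes, and 0 of either met the rule. Cell cycle genes had a median of -0.51 over 7 genes, although Tpx2 was higher (4.02), and 0.33 in the later plates alone. The Notch3-linked and venous endothelial lists had 2 measured genes each and were not placed among random lists, and the other 14 lists lay inside the random range. Without WT plate 044 the count of genes was 1548, without WT plate 468 it was 1135 and without WT plate 469 it was 1460. The earlier plates alone gave 3341 genes and the later plates 1671.

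In endothelial-like cells, vasoactive and interstitial matrix genes were among those higher in KO, while 0 of 14 arterial endothelial genes and 2 of 20 blood-brain barrier genes met the size rule. The mix of cluster 9 and the arterial cluster 16 differed by plate, so the values below compare kinds of cells as well as genotypes. KO plate 043 had 9 cells of cluster 9 and 5 of cluster 16, KO plate 471 had 1 and 16, and WT plate 044 had 2 and 10. WT plate 468 had 45 and 3, and WT plate 469 had 97 and 3. Over 15 genes, smooth muscle transcripts stood at 30.9% and 32.5% of their smooth muscle-like level on KO plates 043 and 471. They stood at 21.6% on WT plate 044, and at 0.120% and 0.441% on WT plates 468 and 469. KO plate 467 had 9 endothelial-like cells and was left out. Of 10146 measured genes, 631 were higher and 498 lower in KO, from 31 KO and 160 WT cells, and plates did not overlap for 21.3% of genes, against the 20% that chance gives for 2 plates against 3.

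Vasoactive receptors and signalling had a median of 3.47 over 12 genes, led by Npy1r (5.20), and Notch3-linked arterial genes 3.42 over 8 genes, led by Rasl12 (5.32) and Heyl (4.92). Medians were 1.60 for contractile apparatus, 1.83 for ion channels and calcium handling, 2.24 for interstitial matrix and elastic fibre, and 0.30 for basement membrane genes. They were 1.04 for arterial endothelial, 1.22 for venous endothelial, 0.70 for immediate early and 0.69 for inflammation and adhesion genes. Blood-brain barrier and transport genes had a median of -1.01 over 20 genes, with 2 lower by the rule, and cholesterol synthesis -0.47 over 15 genes, with 2 genes lower by the rule, among them Fdps (-1.40). The other 10 lists lay inside the random range.

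The named genes that were higher in KO endothelial-like cells were Gem (6.22), P2ry2, Ogn (6.00), Hapln1, Nfil3, Olfr78, Efhd1, Ndst3, Pi16 and Tnfaip2. P2ry2 had 0 counts in WT and was 1197-fold above the floor for a count of 0, in pooled counts. That fold is not a lower limit. Pi16 was a leading gene of cluster 16 and Ndst3 of cluster 2. Olfr78 differed by 0.76 within the earlier batch and 7.68 within the later, and its reads are uncertain, because its exons overlap those of Olfr560. Mapkapk3 and RP23-392I2.3 had 0 counts in KO, 96.9-fold and 88.0-fold lower by such a floor in pooled counts. Dpp4 (-4.56), Fam84b (-4.40), Rtp3, Fgfr1op, Ctdp1, Ifit2, Ece2 and Napepld were also lower. Efhd1, Dpp4, Fam84b and Rtp3 overlap antisense gene models. Between plates 043 and 044, where the WT plate had the larger share of arterial cells, the medians of 7 of the 12 lists outside the random range changed sign, among them blood-brain barrier (0.24) and arterial endothelial genes (-1.33). The count of genes was 2322 without KO plate 043, 2684 without KO plate 471 and 2277 without WT plate 044, 3647 in plates 043 and 044 alone, and 2959 in the later plates alone.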

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

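All tests in this part were chosen only after the result was seen, except those of transcript length and GC content and of smooth muscle cells sorted with endothelial-like cells.

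Some genes and lists differed in opposite directions in different classes, with every KO plate on 1 side of every WT plate for the genes; these differences between classes were not tested. Galnt18 was lower in fibroblast-like (-3.25) and higher in ependymal-like cells (3.58), and so was Raver2 (-2.02 and 4.52), which had 1 count in WT ependymal-like cells, so that the last value depends on the pseudocount. Napepld was higher in fibroblast-like (1.18) and lower in endothelial-like cells (-3.75). The median of the Notch3-linked arterial genes was -0.54 in smooth muscle-like and 3.42 in endothelial-like cells. The contractile apparatus median was -0.11 in smooth muscle-like, 0.91 in fibroblast-like and 1.60 in endothelial-like cells. Within the earlier batch alone it was 0.16 in fibroblast-like and 0.039 in endothelial-like cells. There the Notch3-linked median was 0.57 in endothelial-like cells. Endothelial-like cells of the KO plates and the earlier WT plate held far more smooth muscle transcripts than those of the later WT plates. The list contrasts with endothelial-like cells therefore cannot be assigned to genotype. No group of 3 plates can be searched for an outlying plate by the rule used here.

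Notch3 was lower in smooth muscle-like cells of WT plate 044, at 183 CPM, than of WT plates 468 and 469, at 731 and 1035 CPM. A mislabelled plate stays open. Of 50 other genes with a 4-fold gap between later KO and WT plates, 39 (78%) went the WT way between plates 044 and 043. The 95% interval (64.0 to 88.5) treats genes of a single pair of plates as independent. Since 43 of the 50 were higher in KO, genes that move together could give this share, so it cannot decide. Transcript length and GC bias are argued against as the whole cause, since the 50 genes nearest to Notch3 in both had a median difference of -0.85 (SE 0.101) between plate 044 and the later WT plates, against -2.24 for Notch3, although 1 of them was as low. Such a shift may still account for part of it, and KO plate 043 also had less Notch3 than KO plates 467 and 471 (-0.90), with -0.79 for the matched genes. A different mix of smooth muscle-like clusters is argued against, since the difference was -2.63, -2.34 and -2.01 (SE 0.247, 0.221 and 0.215 over resampled cells) within clusters 1, 4 and 8, although plates 468 and 469 had only 8 to 14 cells in each. The batch stays open, and no biological explanation was tested, since these plates are all WT.

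Smooth muscle transcripts appeared in other classes on plates 043, 044, 467 and 471, most of all in endothelial-like cells. Free smooth muscle RNA spread alike over all classes is argued against as the whole source. Over 15 genes, the highest class, endothelial-like, had at least 86.6 times the share of the lowest on each of these plates. The 86.6 came from plate 467, with 9 endothelial-like cells, and plate 044 gave 89.1. A smaller part from free RNA stays open. Fibroblast-like shares were 1.11% to 2.25% on these plates against 0.319% and 0.166% on plates 468 and 469, while ependymal-like shares overlapped. The size of this contrast depends on the gene. On plate 044 Acta2 was 1315 CPM in endothelial-like, 243 in fibroblast-like and 1104 in ependymal-like cells. Smooth muscle cells sorted together with endothelial-like cells stay open, because the largest interquartile range of the log2 ratio to the smooth muscle-like level over 15 genes was 1.38, between the bounds of 1 and 2 set for either answer. Arterial cluster 16, whose second-best marker list was smooth muscle cell, had a median of 6271.5 detected genes. Cluster 9 had 3991 and the smooth muscle-like clusters 4050 to 4596, which goes with 2 cells per well. However, ependymal-like cluster 3 also had 6263, so gene number does not settle it. Expression of these genes by arterial endothelial-like cells themselves was not tested, and genotype alone leaves WT plate 044 unexplained.

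Immediate early genes were higher in ependymal-like cells of the KO plates. Smooth muscle RNA in these wells is argued against. At its share over 15 genes, it would bring at most 2.54% of the immediate early reads of a KO plate. That share depends on the genes used. On the KO plates Myh11 was 4.00 to 4.44 CPM in ependymal-like and 3311 to 4767 CPM in smooth muscle-like cells. Acta2 would allow more, at 980 to 1276 CPM against 4576 to 6148 CPM. A different mix of ependymal subclusters is argued against for plates 043 and 044, where the list's median was 2.84 within the larger subcluster, from 21 and 9 cells, but not for the later plates, whose WT cells in that subcluster numbered 1. Handling that acts on all cell types of a plate alike stays open: the medians were 0.22 in smooth muscle-like and -0.33 in fibroblast-like cells, but WT levels there, at least 12996 and 3277 CPM for the list, were already high beside the 1771 to 3947 CPM of KO ependymal-like cells. A difference by genotype stays open as well and cannot be told apart from handling of these plates.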

How the results depend on the processing

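The alternatives that weighted clusters 1, 4 and 8 equally, added cluster 2 or left cluster 6 out were chosen only after the data were seen; the others were planned. No paired analysis was possible because the labels named no animals, and plates of the genotypes had no stated pairs. Medians below are log2 differences, KO minus WT, of gene lists, given where they moved by at least the SD over KO plates, or turned in sign for a list outside the random range. Ranges over plates are given for lists with such a move, so smaller turns in sign of other lists are not listed. Unless fewer plates or genes are named as the reason, the cause was not tested.

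Notch3 in smooth muscle-like cells was lower in KO under all 21 alternatives, from -3.31 to -1.67. Of the Notch3 differences over the 4 classes, 71 moved by no more than the SD between plates and 3 by more. For named genes and list examples, 7047 values moved by no more than the SD, 385 by more, and 0 of those for genes that met the rule reversed. Among genes that did not meet it, 190 values had the opposite sign. Leaving plates out, or changing only the fold or expression filter, could not reverse a gene that met the rule, since its plates did not overlap. That includes Notch3 in smooth muscle-like cells, so its steady direction is in part fixed by construction. For list medians, 1468 moved by less than the SD, 263 by more and 23 reversed, the last counted among lists outside the random range. Of the counts of genes or lists, 238 stayed within 1.5 times and 114 did not. Class shares moved by no more than the SD in 145 values and by more in 15.

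Fewer or more genes pass by construction when the expression filter is altered. With 1 CPM and no share of cells, 738 genes (550 higher, 188 lower) met the rule in smooth muscle-like, 1172 (910 higher) in fibroblast-like, 1256 (1020 higher) in ependymal-like and 1805 (1019 higher, 786 lower) in endothelial-like cells. Interferon response had a median of 0.76 and cell cycle 0.15 in smooth muscle-like cells. PDGF and TGF-beta signalling stood at 0.87 in fibroblast-like cells. Interstitial matrix and elastic fibre was at 1.07, arterial endothelial 0.85, interferon response 1.47, inflammation and adhesion 1.47 and cell cycle -0.16 in ependymal-like cells. Interstitial matrix and elastic fibre came to 1.96 and glycolysis -0.041 in endothelial-like cells. With 50 CPM, the counts were 55 (28 and 27), 153 (89 and 64), 121 (71 and 50) and 370 (191 and 179), and 4 lists lay outside the random range in fibroblast-like cells. Cholesterol synthesis had a median of -0.13 in smooth muscle-like cells. Ion channels and calcium handling stood at -0.072, PDGF and TGF-beta signalling 0.11, blood-brain barrier and transport -0.052, arterial endothelial 0.17 and inflammation and adhesion 0.38 in fibroblast-like cells. Interstitial matrix and elastic fibre was at 0.19, PDGF and TGF-beta signalling 0.58 and interferon response 0.23 in ependymal-like cells. Interstitial matrix and elastic fibre came to 1.96, venous endothelial 0.59 and inflammation and adhesion 0.027 in endothelial-like cells.

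A smaller fold also admits more genes by construction. A fold of 1.5 gave 563 genes in smooth muscle-like cells (317 higher, 246 lower), 947 in ependymal-like cells (378 lower), 347 lower genes in fibroblast-like and 812 lower genes in endothelial-like cells. The fold rule alone gave 664 genes (523 higher, 141 lower) in smooth muscle-like, 2284 (1752, 532) in fibroblast-like, 2127 (1672, 455) in ependymal-like and 2503 (1411, 1092) in endothelial-like cells.

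With fewer plates, fewer genes overlap by construction, so more meet the size rule. Plates 043 and 044 alone gave 423 genes (172 lower) in smooth muscle-like, 2284 (1335 higher, 949 lower) in fibroblast-like, 3341 (1885, 1456) in ependymal-like and 3647 (1988, 1659) in endothelial-like cells. Lists outside the random range numbered 3 in fibroblast-like and 5 in endothelial-like cells, and Notch3 differed by -0.44 in ependymal-like and -3.44 in endothelial-like cells. Notch pathway had a median of -0.32, vasoactive receptors and signalling -0.12, venous endothelial 0.41, heat shock -0.0032, interferon response 0.26 and oxidative phosphorylation -0.37 in smooth muscle-like cells. Cytosolic ribosome had a median of -0.20 in smooth muscle-like cells. Notch3-linked arterial genes stood at -0.35, contractile apparatus 0.16, ion channels and calcium handling -0.15, basement membrane 0.13, PDGF and TGF-beta signalling 0.24 and blood-brain barrier and transport -0.34 in fibroblast-like cells. Arterial endothelial stood at -0.0041, immediate early -1.11, heat shock -0.25, endoplasmic reticulum stress 0.12, interferon response -0.49 and inflammation and adhesion 0.010 in fibroblast-like cells. Oxidative phosphorylation stood at -0.15 and cytosolic ribosome -0.15 in fibroblast-like cells. Notch pathway was at -0.14, contractile apparatus 0.12, vasoactive receptors and signalling 1.49, heat shock 0.0060, interferon response -0.016 and inflammation and adhesion -0.096 in ependymal-like cells. Cholesterol synthesis was at 0.60 and cytosolic ribosome 0.018 in ependymal-like cells. Notch pathway came to 0.18, Notch3-linked arterial genes 0.57, contractile apparatus 0.039, ion channels and calcium handling -0.50, vasoactive receptors and signalling 0.26 and interstitial matrix and elastic fibre -0.12 in endothelial-like cells. PDGF and TGF-beta signalling came to 0.094, blood-brain barrier and transport 0.24, arterial endothelial -1.33, venous endothelial -0.017, immediate early -0.23 and endoplasmic reticulum stress -0.29 in endothelial-like cells. Interferon response came to -0.58, inflammation and adhesion -0.22, oxidative phosphorylation -0.36, glycolysis -0.064, cholesterol synthesis -1.18 and cell cycle 1.03 in endothelial-like cells.

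The later plates alone gave 851 genes (558 higher, 293 lower) in smooth muscle-like, 2099 (1242, 857) in fibroblast-like, 1671 (1082, 589) in ependymal-like and 2959 (1480, 1479) in endothelial-like cells, where Notch3 differed by 1.46. Contractile apparatus had a median of -0.031, oxidative phosphorylation -0.024, cholesterol synthesis -0.46 and cell cycle 0.048 in smooth muscle-like cells. Ion channels and calcium handling stood at -0.098, vasoactive receptors and signalling -0.14, basement membrane -0.42, blood-brain barrier and transport -0.37, immediate early 0.23 and endoplasmic reticulum stress 0.092 in fibroblast-like cells. Interferon response stood at 0.23, inflammation and adhesion 1.98 and oxidative phosphorylation 0.16 in fibroblast-like cells. Notch pathway was at -0.23, interstitial matrix and elastic fibre 0.80, heat shock 0.29, oxidative phosphorylation 0.22 and cell cycle 0.33 in ependymal-like cells. Notch pathway came to 0.51, Notch3-linked arterial genes 5.14, contractile apparatus 2.65, ion channels and calcium handling 2.13, vasoactive receptors and signalling 5.01 and interstitial matrix and elastic fibre 3.98 in endothelial-like cells. PDGF and TGF-beta signalling came to 0.80, blood-brain barrier and transport -2.14, arterial endothelial 2.59, venous endothelial 1.97, immediate early 1.86 and heat shock 0.53 in endothelial-like cells. Endoplasmic reticulum stress came to 0.15, interferon response -0.092, inflammation and adhesion 1.91, oxidative phosphorylation 0.021, glycolysis 0.15 and cholesterol synthesis -0.073 in endothelial-like cells. Cell cycle came to -0.083 in endothelial-like cells.

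Leaving out each plate in turn gave 319 to 853 genes in smooth muscle-like cells, 221 to 555 higher and 98 to 298 lower. The counts past 1.5 times were those without WT plate 044 (853), KO plate 043 (431) and WT plate 469 (415). Notch pathway ranged over -0.32 to 0.0080, PDGF and TGF-beta signalling 0.11 to 0.31, contractile apparatus -0.20 to -0.070, arterial endothelial -0.26 to 0.34 and heat shock 0.011 to 0.21. Blood-brain barrier and transport ranged over 0.0070 to 0.30, cell cycle -0.29 to 0.060, vasoactive receptors and signalling -0.19 to 0.087 and interferon response 0.16 to 0.52.

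In fibroblast-like cells the range was 838 to 1918 genes, 558 to 1200 higher and 280 to 718 lower, with 995 without KO plate 043, 1918 without WT plate 044, 1177 without WT plate 468 and 1257 without WT plate 469. Between 3 and 7 lists lay outside the random range. Notch3-linked arterial genes ranged over -0.16 to 0.51, vasoactive receptors and signalling -0.30 to 0.43, basement membrane -0.39 to 0.10, PDGF and TGF-beta signalling 0.44 to 0.92 and oxidative phosphorylation -0.070 to 0.14. Ion channels and calcium handling ranged over -0.40 to 0.29, blood-brain barrier and transport -0.57 to 0.051, immediate early -0.63 to 0.0035, endoplasmic reticulum stress -0.056 to 0.25 and interferon response -0.067 to 0.37. Arterial endothelial ranged over -0.13 to 0.77, heat shock -0.021 to 0.38, inflammation and adhesion 0.37 to 1.92 and cell cycle 0.078 to 0.95. The sign turned without WT plate 468 for basement membrane (0.10) and arterial endothelial (-0.13), without WT plate 044 for blood-brain barrier (0.051) and without KO plate 467 for immediate early genes (0.0035).

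Ependymal-like cells gave 827 to 1548 genes, 551 to 991 higher and 276 to 557 lower, with 1548 without WT plate 044, 1460 without WT plate 469 and 1135 without WT plate 468. Notch pathway ranged over -0.35 to 0.040, contractile apparatus 0.38 to 0.61, interstitial matrix and elastic fibre 0.10 to 0.98, interferon response 0.45 to 0.84 and cell cycle -0.58 to -0.18. Ion channels and calcium handling ranged over -0.24 to 0.36, basement membrane -0.15 to 0.43, heat shock 0.079 to 0.36 and blood-brain barrier and transport -0.34 to 0.19. Endothelial-like cells gave 1441 to 2684 genes, 825 to 1317 higher and 616 to 1367 lower, with 2684 without KO plate 471, 2322 without KO plate 043 and 2277 without WT plate 044. Notch pathway ranged over -0.063 to 0.40, contractile apparatus 1.39 to 2.35, ion channels and calcium handling 0.93 to 2.04, interstitial matrix and elastic fibre 1.54 to 3.55 and PDGF and TGF-beta signalling 0.45 to 0.83. Venous endothelial ranged over 0.61 to 1.28, glycolysis -0.12 to 0.049, endoplasmic reticulum stress -0.12 to 0.15, Notch3-linked arterial genes 2.51 to 4.71 and vasoactive receptors and signalling 2.64 to 4.67. Arterial endothelial ranged over 0.51 to 1.81, interferon response -0.36 to -0.15 and cell cycle -0.079 to 0.70.

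How cells were classed changed some results, and marker levels without clusters gave 582 genes in fibroblast-like cells, 324 of them shared with the 639. With classes from marker levels without clusters, smooth muscle-like cells were 68.4% of KO cells, pericyte-like 1.95%, astrocyte-like 0.533% and macrophage/microglia-like 0.0882%, and fibroblast-like cells were 4.98% of WT cells. Contractile apparatus had a median of -0.19, immediate early -0.015 and heat shock 0.051 in smooth muscle-like cells. Basement membrane stood at 0.24, PDGF and TGF-beta signalling 0.22, blood-brain barrier and transport -0.42, venous endothelial 0.31, heat shock 0.12 and interferon response 0.29 in fibroblast-like cells. Inflammation and adhesion was at 1.18 in ependymal-like cells. Notch pathway came to 0.13, ion channels and calcium handling 1.12, vasoactive receptors and signalling 2.36, interstitial matrix and elastic fibre 1.92, interferon response -0.13 and glycolysis 0.099 in endothelial-like cells. Cytosolic ribosome came to -0.15 and cell cycle 0.11 in endothelial-like cells. Without the cells with markers of a second class, 1217 genes met the rule in endothelial-like cells, 794 of them shared with the 1129. In fibroblast-like cells 1236 genes (808 higher, 428 lower) met it and 3 lists lay outside the random range, but WT plate 468 then held 9 of these cells and dropped out. Plate 468 left out alone gave 1177 genes, and the fibroblast-like values that follow also rest on these fewer plates. Notch3-linked arterial genes stood at 0.0057, basement membrane 0.21, PDGF and TGF-beta signalling 0.42, blood-brain barrier and transport -0.072, arterial endothelial -0.076 and heat shock 0.0021 in fibroblast-like cells. Endoplasmic reticulum stress stood at -0.083, interferon response -0.12, inflammation and adhesion 0.063 and cholesterol synthesis 0.14 in fibroblast-like cells. Interferon response was at 0.70 in ependymal-like cells. Notch pathway came to 0.22, ion channels and calcium handling 2.42, PDGF and TGF-beta signalling 0.41, endoplasmic reticulum stress 0.18 and glycolysis -0.019 in endothelial-like cells. At resolution 2 a single list median moved, and a neuron-like cluster of 19 cells was named. Blood-brain barrier and transport had a median of 0.29 in smooth muscle-like cells.

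With clusters 1, 4 and 8 weighted equally, the count was 303 genes, 160 of them shared with the 275. Contractile apparatus had a median of -0.018, interstitial matrix and elastic fibre 0.36, PDGF and TGF-beta signalling -0.040, immediate early -0.14, heat shock -0.051 and cholesterol synthesis -0.61 in smooth muscle-like cells. As a separate alternative, cluster 2 was added to the 6 clusters of the class. Immediate early had a median of -0.017 and heat shock 0.051 in smooth muscle-like cells. In another, cluster 6 alone was left out of them. Contractile apparatus had a median of -0.046, PDGF and TGF-beta signalling 0.13 and heat shock 0.018 in smooth muscle-like cells.

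Scaling and weighting moved few medians. DESeq2 size factors gave 275 genes in smooth muscle-like cells, 272 of them shared. With these factors endoplasmic reticulum stress stood at -0.078 in fibroblast-like cells. A pseudocount of 5 CPM pulls values toward 0 by construction. Blood-brain barrier and transport stood at -0.33 in fibroblast-like cells. Notch3-linked arterial genes came to 2.76, ion channels and calcium handling 1.02, vasoactive receptors and signalling 2.54 and cell cycle 0.21 in endothelial-like cells. Equal weight for each cell moved 4 medians. Interferon response was at 0.69 in ependymal-like cells. PDGF and TGF-beta signalling came to 0.47, venous endothelial 1.53 and glycolysis 0.039 in endothelial-like cells. Thinning to 50000 counts moved 11, and it shared 448 of 670 genes in fibroblast-like and 440 of 689 in ependymal-like cells with the 639 and 609. Notch pathway had a median of -0.055 and contractile apparatus -0.057 in smooth muscle-like cells. Endoplasmic reticulum stress stood at 0.059 and cell cycle 0.57 in fibroblast-like cells. Notch pathway was at 0.28, interstitial matrix and elastic fibre 0.64 and cell cycle -0.25 in ependymal-like cells. Notch pathway came to 0.14, PDGF and TGF-beta signalling 0.43, venous endothelial 1.48 and glycolysis 0.064 in endothelial-like cells.

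Other cell filters, each with its own clustering and naming, moved some shares. With at least 100000 counts and 1500 genes, pericyte-like cells were 3.18% of KO cells. Blood-brain barrier and transport had a median of 0.30 and cell cycle 0.18 in smooth muscle-like cells. With at least 10000 counts and 500 genes, which kept 2254 instead of 2252 cells, the move came from the new clusters and names and hardly from the 2 cells. Pericyte-like cells were 6.02% of KO and 4.61% of WT cells, and smooth muscle-like cells 60.3% of KO cells. Plate 043 alone had 16.4% fibroblast-like cells, and plate 044 alone had 81.8% smooth muscle-like, 0.528% pericyte-like, 0.264% macrophage/microglia-like, 0% astrocyte-like and 0% oligodendrocyte-like cells, by construction as single plates. Some classes had few cells, with 10 ependymal-like, 11 fibroblast-like and 12 endothelial-like cells on the WT plate with the fewest of each. The compared KO endothelial-like cells numbered 31 in all.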

Other observations

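All tests in this part were chosen only after the result was seen.

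Splits of the 6 plates into 3 against 3 number 10, too few for a share under 0.05. In smooth muscle-like cells the genotypes gave 275 genes and the highest other split 462, and 5 of the 10 splits, that of the genotypes included, gave as many. The split with 462 set plates 043, 044 and 468 against the others and follows the batch in part. Within plates 043 and 044 the genotypes gave 423 genes and within the later plates 851. Those counts rest on fewer plates, where more genes meet the rule by construction, so they cannot be set against 462. In fibroblast-like cells the genotypes gave 639 genes and the highest other split 919, and 5 splits gave as many, the real one included. In ependymal-like cells these values were 609, 764 and 4, again with the real split counted.

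Counting only smooth muscle-like genes with a gap between the nearest plates of the genotypes, a 2-fold gap gave 30 genes against 34 in the highest other split, with 2 splits as large, the real one included. A 3-fold gap gave 17 against 4 and a 4-fold gap 10 against 2, each with 1 split as large, the real one. In fibroblast-like cells a 2-fold gap gave 115 against 85, and in ependymal-like cells 103 against 84. In endothelial-like cells it gave 248 against 640, for plates 468 and 469 against the others, which points to a structure of the plates other than genotype. These splits are also too few for a share under 0.05.

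A hypothesis was that DNA of another strain, carried along with the targeted allele, may alter genes near Notch3 on chromosome 17. Within 5 Mb, 3.85% of measured genes met the size rule in smooth muscle-like cells (5 of 130; 95% interval 1.26 to 8.75), against 2.90% elsewhere. Within 10 Mb it was 2.30% against 2.93%. The genes were Pim1, Btbd9, Zfp799, Dxo and Gm17276, which overlaps Notch3 itself, and these counts were too few to decide.

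Acta2 in ependymal-like cells, averaged per plate, was 927, 1323 and 1103 CPM on KO plates 043, 467 and 471, 1104 CPM on WT plate 044, and 91.1 and 208 CPM on WT plates 468 and 469. The table's GFP entry held 1 read, in 1 KO cell.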
